A study of Homo sapiens with 96 samples.

How the data were processed

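Gene expression was measured in LAPC4, a human prostate cancer cell line that carries an androgen receptor, on 96 Illumina Human HT-12 v4 arrays. Cells were exposed for 6 h to 0.05% DMSO, to 0.33 nM of the synthetic androgen R1881, or to R1881 together with 1 of 28 chemicals, per the labels' protocols. DMSO and R1881 alone had 6 arrays each, numbered 1 to 3 and 1b to 3b in the labels, and every chemical had 3, numbered 1 to 3. The dose was 20 uM for most chemicals, 10 uM for Androstenedione, Dexamethasone, Mifepristone, Progesterone and Triticonazole, and 0.5 uM for Dihydrotestosterone, MethylTestosterone, Norethindrone, Testosterone propionate and Trenbolone. Per the series' design text, 3 experiments were run on separate days and the samples were hybridized in random order without knowledge of the treatment. The labels do not say which array belongs to which day, nor what sets the arrays 1 to 3 of the controls apart from 1b to 3b. Of the 10 closest of 114 pairs of arrays of a group, 5 were among the 6 pairs of control arrays of the same number and 5 were arrays of a chemical with different numbers, so these values do not settle whether 1b to 3b are repeat runs, and they were used as separate samples. The p-values therefore measure only the spread between these samples, which may be partly technical.

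The authors scanned the arrays with iScan 3.3.28 and used GenomeStudio and Partek Genomics Suite, per the series' design text, and limma is named in the submitters' processing notes. The deposited values are on a log2 scale, as judged from their range of 6.3157 to 14.152 in the table. Their quantiles were nearly equal in all arrays, with medians of 6.7211 to 6.7212, which fits a quantile normalization, so no further normalization was applied. The background correction is not given in the sources used here, and detection p-values per probe were not used here, so the distance of a dim probe from its background is not known. The values were used as deposited. For arrays, it is their number that limits the precision of a group mean.

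The table held 48107 probes. Of these, 30121 are listed in the platform annotation used here, 30113 with 1 gene symbol and 8 with several, and 17986 are not listed and stayed unnamed. Entrez identifiers matched a reference gene for 30074 probes, and 0 symbols changed. Probes whose value lay above the median of its own array (50th percentile) in at least 3 arrays were kept, which left 43820 and dropped 4287. Each gene was represented by the brightest of its kept probes by the mean over all arrays, which gave 18571 genes. There were 191 missing values in 174 probes, and 19 tested genes had any; they were left out array by array. For 48 of the named combinations of gene and comparison another probe of the gene was kept. Of 81 such probes, 6 had the opposite sign, all of them dim. These were probes of STEAP1 under R1881, of ABCG1 under Finasteride, of SGK1 under Flutamide, of F3 under Testosterone propionate and of SPATA31A1 under Trenbolone.

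One linear model with a mean per group was fitted to all 96 arrays with limma 3.58.1 (lmFit, contrasts.fit and eBayes, R 4.3.3), so that all groups shared an estimate of the spread. Tables were read with data.table (version 1.17.8). R1881 was compared with DMSO, each of 28 chemicals given with R1881 was compared with R1881 alone, and 19 pairs of related chemicals at equal dose were compared directly. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the genes of a comparison, with a threshold of 0.05, and errors of log2 changes are standard errors (SE) from the same model. The numbers of genes that also changed at least 1.5-fold were counted as well.

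The androgen index is the mean log2 value of an array over 38 measured genes of a list of 43 androgen-induced genes. It was compared with an exact permutation test (two-sided), in which 3 arrays against 6 cannot give a p below 0.0238 and 3 against 3 none below 0.1, with Benjamini-Hochberg adjustment over the 28 chemicals. For pairs the 95% interval of the difference came from the residual SD of the index over all groups. The share of the R1881 response left was measured on genes that changed at least 1.5-fold at adjusted p under 0.05 between R1881 and DMSO in arrays 1 to 3, in each array of a chemical against the arrays 1b to 3b of both controls, so that the same arrays did not both select and measure, unless 1b to 3b repeat 1 to 3. Selection gave 5 genes (C1orf116, DIO2, FKBP5, SGK1 and UGT2B11), whose mean response in the other controls was 2.06 on the log2 scale.

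The 27 gene lists held 378 genes, of which 345 were measured, or 397 and 362 entries where genes in several lists are counted in each. They were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 783 combinations of list and comparison. Camera with an estimated correlation and fry were run as alternatives. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. The lists, the tests, the samples in each fit and the rule for naming genes were fixed before the data were examined. For R1881 against DMSO the rule takes the 12 genes with the largest increase and the 12 with the largest decrease at adjusted p under 0.05 whose 6 R1881 arrays lie on the same side of the DMSO mean. For each chemical it takes 3 in each direction and for each pair 2, and members of the lists may be named as examples. The result of 1 gene that the rule takes is not reported here.

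The calculations were tested on simulated data made from the group means and spread of the 18571 genes. For R1881 against DMSO, 52.2%, 71.6% and 93.9% of genes changed 1.5-fold, 2-fold and 3-fold were called, and 10 unchanged genes were called as well. For Apigenin, simulated to leave 40% of such a response, 26.9%, 43.3% and 62.1% were called, with 0 unchanged genes. For Atrazine, simulated as unchanged, there were 0 calls. A simulated share of 40% was recovered as 39.5% over the chemicals, and a full response as 98.5%, with 113 genes selected.

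Arrays with the same number deviated together in part of the groups. Correlations across genes of the deviations from the group means between DMSO and R1881 arrays of the same number were 0.76, 0.77 and 0.90. In 12 chemicals (Apigenin, Atrazine, Cyproterone acetate, DDE, Dehydroepiandrosterone, Fenitrothion, Finasteride, Iprodione, Linuron, Procymidone, Tebuconazole and Triticonazole) all 3 correlations with R1881 were over 0.1, and there the number was taken to pair the arrays. The pairing comes from these correlations and not from the labels. With the number as a replicate block, R1881 against DMSO gave 29 genes in place of 23.

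Other settings fixed at the same time were cyclic loess (fast method) with median centring, the replicate block, no filter, a stricter filter (70th percentile), a fit to only the groups compared, every probe in place of the brightest, either part of the controls alone, and leaving out each array in turn. Further settings were chosen after seeing the data, among them control arrays of the same number averaged as 1 sample, as was the count of genes lower under a chemical that R1881 raised, for which 100 sets of unchanged chemicals were simulated. Each array was assigned to the nearer of 2 median profiles over 9276 bright genes, which started from the arrays numbered 3 and all others and were updated until no array moved; 100 random starts, added later, ended in the same clusters. This gave clusters of 34 and 62 arrays that cut across the groups, and 6 arrays correlated under 0.9 with the median profile of their cluster. The fits were repeated without these 6 arrays and with the cluster as a block. In all, 9 versions of left-out arrays and blocks were looked at, 7 of them added after seeing the data. They left out 0, 2, 6 or 7 arrays, and the limit of 0.9 was settled after the numbers of called genes under the others were known. A stricter limit was also started, but its run gave no output. The fits to all 96 arrays stayed the main result.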

Results

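LAPC4 cells were exposed for 6 h to DMSO, to the synthetic androgen R1881 at 0.33 nM, or to R1881 together with 1 of 28 chemicals, and transcripts were measured on 96 arrays. The chemicals were pharmaceutical antiandrogens, natural and synthetic steroids, fungicides and other pesticides, a plant flavonoid and an industrial chemical. The series' title asks which of them modulate the androgen receptor. DMSO and R1881 alone had 6 arrays each and every chemical had 3, in 30 groups. Values are log2 intensities of 18571 genes, and each array's median lay between 6.7211 and 6.7212.

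Arrays differed in ways that the groups do not describe. Most arrays resembled either of 2 profiles, with 34 arrays in cluster A and 62 in cluster B, and the labels' numbers were spread unevenly over them. Of the arrays numbered 3, 23 lay in cluster A, against 11 numbered 1 and 0 numbered 2 (Fisher's exact test, p = 2.26e-07). For cluster B minus cluster A, the median log2 difference was 0.28 for ribosome biogenesis genes, 0.225 for ATF4 target genes, -0.31 for the androgen-repressed list and 0.00 for the androgen-induced list. In addition, 6 arrays correlated under 0.9 with the profile of their cluster, namely Trenbolone 2 (0.46), Spironolactone 2 (0.59), Flutamide 3 (0.75), Testosterone propionate 2 (0.83), MethylTestosterone 2 (0.85) and Apigenin 2 (0.89). The luminal epithelium markers lay -2.82, -2.47, -1.18, -1.04, -0.0067 and -0.65 from the cluster median in these arrays, in the same order. All arrays entered the values given here unless a reduced fit is named. The reduced fit left out these 6 arrays and took the cluster as a block, and it was chosen after seeing the data.

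**Figure D1:**
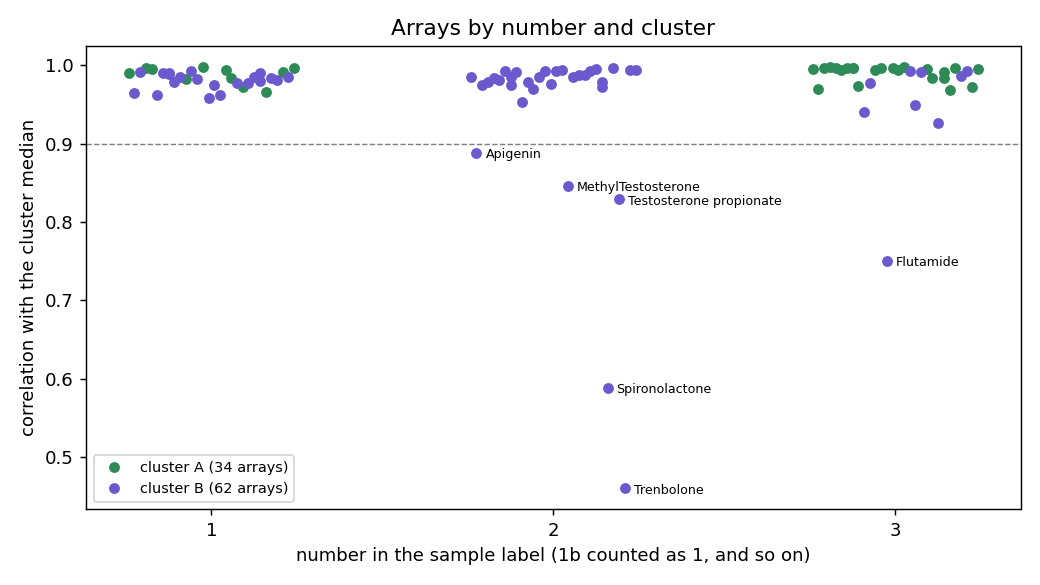
Correlation of each array with the median profile of its cluster (vertical axis), by the number in its label (horizontal axis, with 1b counted as 1) and coloured by cluster. The dashed line marks 0.9, and the 6 labelled arrays lie under it, from 0.46 for Trenbolone 2 to 0.89 for Apigenin 2.

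R1881 against DMSO asks which transcripts the androgen itself changed in these cells. The level of SGK1, a kinase known as a target of steroid receptors, went from 8.91 ± 0.07 to 11.79 ± 0.21 (SD, n = 6 each), an increase of 2.88 on the log2 scale or 7.35-fold (SE 0.35, adjusted p = 3.97e-08). C1orf116 rose by 2.36 (SE 0.34), FKBP5, a co-chaperone of steroid receptors, by 1.90 (SE 0.23), and NPPC, the precursor of C-type natriuretic peptide, by 1.89 (SE 0.29). NDRG1, a stress-responsive gene, rose by 1.77 (SE 0.31), the prostate surface protein gene STEAP1 by 1.76 (SE 0.41, adjusted p = 0.047, but 0.0515 without the filter on dim probes), UGT2B11, a glucuronosyltransferase, by 1.70 (SE 0.11, adjusted p = 8.78e-20), and DIO2, which activates thyroid hormone, by 1.55 (SE 0.19). S100P, a calcium-binding protein gene, rose by 1.45, the potassium channel gene KCNK13 by 1.42 and EAF2, an elongation factor partner, by 1.25. CAMK2N1, an inhibitor of a calmodulin-dependent kinase, was the gene that fell, by 0.85 (SE 0.19, adjusted p = 0.0263). By limma 22 genes were higher and 1 lower at adjusted p under 0.05, all by at least 1.5-fold, and 248 had unadjusted p under 0.05. The reduced fit, with equal changes and smaller SE, gave 137 and 46.

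Of the 38 measured genes of the androgen-induced list, 9 rose over all genes tested and 21 when adjusted over the list alone, 36 had a positive change, and the median change was 0.40 (camera, adjusted p = 7.74e-84, and adjusted p = 1.2e-09 with an estimated correlation). Among the 9 were SGK1, C1orf116, FKBP5, NDRG1, EAF2, the kallikrein genes KLK2, which rose by 1.22 (adjusted p = 0.00154), and KLK4, which rose by 1.16 (adjusted p = 0.00233), and HPGD, a prostaglandin-degrading enzyme, at 0.91 (adjusted p = 0.00134). TMPRSS2 at 0.95 (adjusted p = 0.135), PMEPA1 at 0.94 (adjusted p = 0.0982), ZBTB16 at 1.25 (adjusted p = 0.961) and KLK3, the gene of prostate-specific antigen, at 0.10 (adjusted p = 1) did not pass. The glucocorticoid response list shares FKBP5, SGK1, ZBTB16 and ERRFI1 with it, and 3 of its 18 genes rose, or 6 when adjusted over the list alone (adjusted p = 2.69e-29, and adjusted p = 3.99e-05 with an estimated correlation). These were FKBP5, SGK1 and the transcription factor gene CEBPD at 0.90 (adjusted p = 0.00134). The hypoxia and glycolysis list (adjusted p = 0.00652, but adjusted p = 0.166 with an estimated correlation) was called upward with NDRG1 as its 1 member that rose. The basal epithelium markers were called upward (adjusted p = 0.0131, but adjusted p = 0.351 with an estimated correlation) and the mitotic list downward (adjusted p = 0.0162, but adjusted p = 0.769 with an estimated correlation), both without a member that passed alone. The androgen-repressed list of 11 genes was not called (adjusted p = 0.866), and its members UGT2B11 and CAMK2N1 went opposite ways.

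The androgen index, the mean log2 value of the androgen-induced list in an array, was 8.78 ± 0.09 under R1881 and 8.08 ± 0.06 under DMSO (SD, n = 6 each; exact permutation test, p = 0.002165). Under 18 of the 28 chemicals the index lay below R1881 alone in all 3 arrays with p = 0.0238 by the exact permutation test, the smallest that 3 against 6 arrays can give, and adjusted p = 0.0370. If control arrays of the same number are repeat runs of 1 sample, which was not settled, 3 controls remain, the exact test cannot go below 0.1, also for R1881 against DMSO, and none of the 18 passes. Camera called the list downward under these 18 and Cyproterone acetate, but with an estimated correlation not under Cyproterone acetate (adjusted p = 0.223), Progesterone (adjusted p = 0.456) and Spironolactone (adjusted p = 0.206), which were called with it in the reduced fit (adjusted p = 0.00861, 0.0285 and 0.00162). The difference from R1881 alone was -0.79 for Apigenin, -0.78 for Spironolactone, -0.71 for Fenitrothion, -0.70 for Procymidone, -0.59 for Vinclozolin, -0.56 for BisphenolA, -0.55 for Bicalutamide and Flutamide, and -0.51 for Linuron. It was -0.50 for Dehydroepiandrosterone, -0.49 for Triticonazole, -0.47 for Prochloraz, -0.44 for Finasteride, -0.41 for DDE, -0.36 for Tebuconazole, -0.31 for Mifepristone, -0.30 for Hydroxyflutamide and -0.21 for Progesterone. Cyproterone acetate at -0.16 did not pass (exact permutation p = 0.0476, adjusted p = 0.0702). Spironolactone stood at -0.48 and Apigenin at -0.66 in the reduced fit.

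For the remaining 9 chemicals the exact test did not separate the index from R1881 alone. Dihydrotestosterone, a natural androgen, lay 0.11 higher with all 3 arrays above the R1881 mean (p = 0.167, exact permutation), Androstenedione at 0.0047 (0.929), Atrazine at -0.0049 (0.929), Dexamethasone at -0.010 (0.857), Norethindrone at -0.021 (0.69) and Iprodione at -0.066 (0.31), with all 3 arrays below that mean. Under MethylTestosterone the difference was -0.08 (exact permutation p = 0.524), under Testosterone propionate -0.21 (0.5) and under Trenbolone -0.39 (0.643), each with 1 array below the R1881 mean, which was array 2 at 8.39, 8.07 and 7.41. Without those arrays, in the reduced fit, these differences were 0.06, 0.06 and 0.10.

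**Figure D2:**
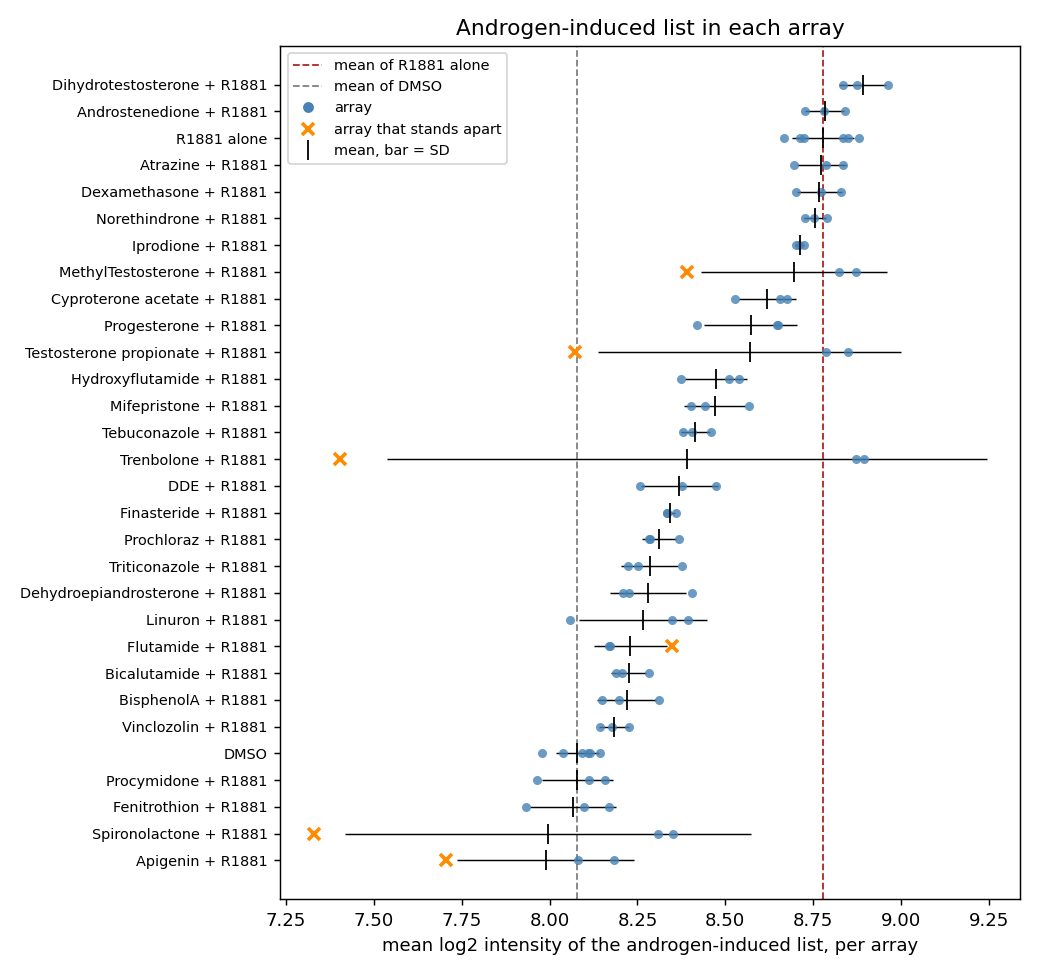
Androgen index of each array (horizontal axis, mean log2 intensity of 38 androgen-induced genes) in each group, with the group mean and SD and crosses for the 6 arrays that stand apart. The 6 R1881 arrays average 8.78 and the 6 DMSO arrays 8.08, and all 3 arrays of Procymidone (mean 8.08) and Fenitrothion (mean 8.07) lie near DMSO.

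The share of the R1881 response left was measured on 5 genes (C1orf116, DIO2, FKBP5, SGK1 and UGT2B11) with the controls split, where 0% is DMSO and 100% R1881 alone (values ± SD, n = 3). It was -4.1% ± 4.1 under Procymidone, -1.9% ± 6.4 under Apigenin, -1% ± 5.2 under Fenitrothion, 5.7% ± 11.3 under Vinclozolin, 7.2% ± 6 under Flutamide and 7.9% ± 21.3 under Spironolactone. BisphenolA left 11.2%, Bicalutamide 12.5%, Triticonazole 23.5%, Prochloraz 25.1%, Dehydroepiandrosterone 25.9%, Finasteride 30.6%, Linuron 31.1%, DDE 42.5%, Tebuconazole 42.6%, Hydroxyflutamide 49.1%, Mifepristone 55.1%, Cyproterone acetate 64.1% and Progesterone 74.7%. The other chemicals left between 79.6% (Trenbolone, SD 67.1) and 121.6% (Dihydrotestosterone, SD 7.4). With 3 arrays against 3 the exact test cannot go below 0.1, so no share was called. In the reduced fit, with 59 genes, Spironolactone stood at 25.7%, Apigenin at 10.5% and Trenbolone at 120.5%.

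**Figure D3:**
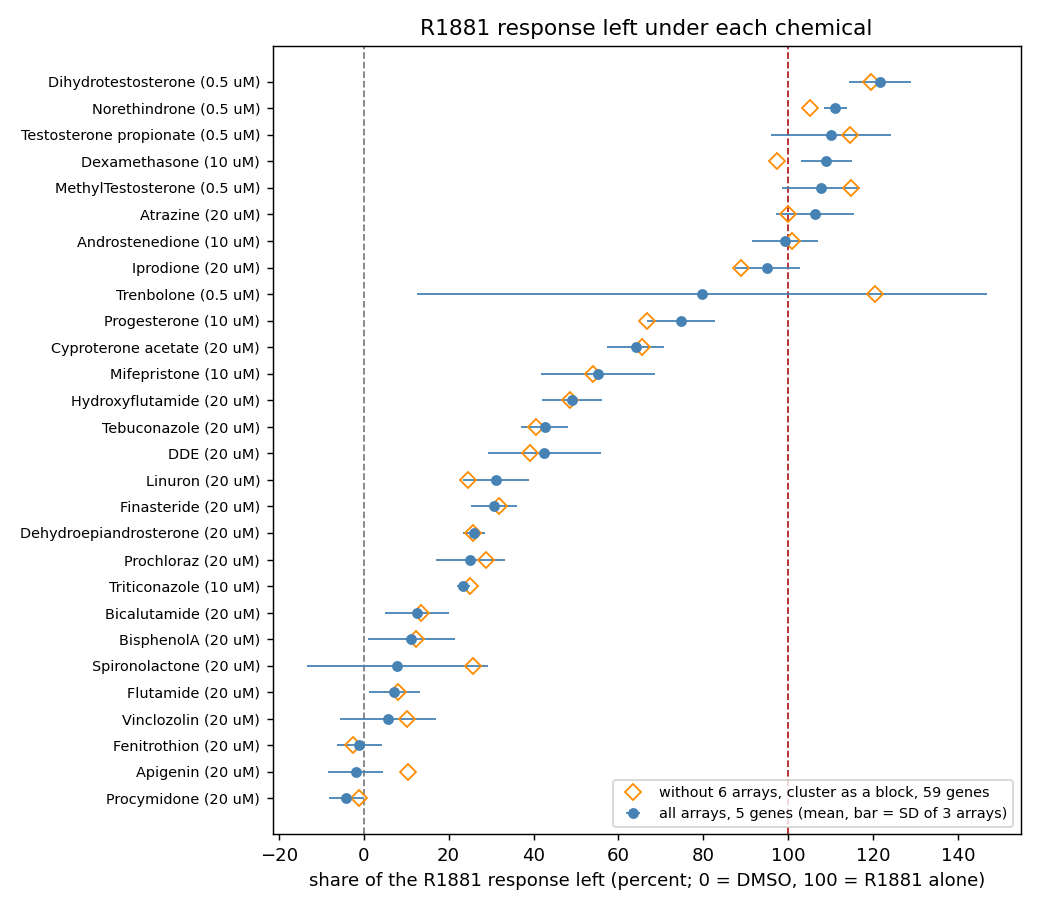
Share of the R1881 response left under each chemical (horizontal axis, percent, 0 for DMSO and 100 for R1881 alone), as mean and SD of 3 arrays over 5 genes, with open diamonds for the reduced fit over 59 genes. Values run from -4.1% under Procymidone to 121.6% under Dihydrotestosterone, and Trenbolone has the widest bar (SD 67.1).

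The comparisons of single genes against R1881 alone ask what each chemical changed beyond the androgen. In 21 chemicals limma called a gene lower, and in 15 of them every such gene was among the 22 that R1881 raised. The exceptions were Bicalutamide (7 of 8), Flutamide (8 of 10), Apigenin (18 of 175), Spironolactone (18 of 1834), Trenbolone (2 of 675) and Testosterone propionate (0 of 1). The R1881 arrays enter both comparisons, and simulated unchanged chemicals shared at most 1 such gene; with the R1881 arrays split, every gene called lower was among 6 that R1881 raised in 11 of the 15. It was 5 of 6 under Procymidone, 4 of 6 under Fenitrothion, BisphenolA and Bicalutamide, 2 of 3 under Linuron, 4 of 4 under Flutamide, 5 of 70 under Apigenin and 6 of 1068 under Spironolactone. With same-numbered controls averaged, an alternative chosen after seeing the data, it was 5 of 5 under Procymidone and 4 of 5 under Fenitrothion, among 5.

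The dicarboximide fungicides Procymidone and Vinclozolin and the organophosphate Fenitrothion lowered genes of this kind. SGK1 fell under Procymidone (-3.07, SE 0.43, adjusted p = 4.18e-06, n = 3), Fenitrothion (-3.09, adjusted p = 4.99e-06) and Vinclozolin (-2.67, adjusted p = 0.000144). C1orf116 fell in the same order (-2.38, -2.25 and -1.99), FKBP5 fell under Procymidone (-2.18) and Fenitrothion (-1.97), and NDRG1 fell under Vinclozolin (-2.03). Limma called 0 genes higher and 9 lower under Procymidone (241 at unadjusted p under 0.05), 0 and 9 under Fenitrothion (213), and 0 and 8 under Vinclozolin (178). The reduced fit gave 40 higher and 92 lower, 14 and 88, and 35 and 64. Under cyclic loess 22.2% of the Vinclozolin calls were upward.

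The antiandrogen drugs Bicalutamide, Flutamide and Hydroxyflutamide were given at 20 uM. NDRG1 fell under Bicalutamide (-2.45, SE 0.38, adjusted p = 0.000114) and Flutamide (-2.08), as did SGK1 (-2.36 and -2.54), while C1orf116 fell by 1.97 under Bicalutamide and FKBP5 fell by 2.15 under Flutamide. Under Hydroxyflutamide UGT2B11 fell by 1.05 (SE 0.13, adjusted p = 8.4e-07) and CT47A6, a cancer-testis antigen gene, rose by 0.32 (SE 0.06, SD 0.33, adjusted p = 0.00975). Limma called 0 higher and 8 lower genes under Bicalutamide (211 at unadjusted p under 0.05), 0 and 10 under Flutamide (1034), and 1 and 1 under Hydroxyflutamide (299). These became 12 and 67, 12 and 50, and 11 and 26 in the reduced fit. Cyclic loess moved the upward share from 0% to 21.3% under Flutamide and from 50% to 0% under Hydroxyflutamide. The count under Flutamide was 132, 226 and 6 without arrays 1, 2 and 3 in turn, that under Hydroxyflutamide 1, 24 and 12, and that under Bicalutamide 4 without array 1.

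Under BisphenolA, a plastics monomer, SGK1 (-2.40, SE 0.43, adjusted p = 0.0014), NDRG1 (-2.17) and FKBP5 (-1.98) fell. Under the herbicide Linuron S100P (-1.61, SE 0.28, adjusted p = 0.00126), FKBP5 (-1.44) and DIO2 (-1.43) fell, and under DDE, a metabolite of DDT, DIO2 (-1.33) and UGT2B11 (-1.06). Of the azole fungicides, Prochloraz lowered NDRG1 (fell by 1.88), FKBP5 (fell by 1.57) and UGT2B11 (fell by 1.56), Triticonazole SGK1 (fell by 2.21), DIO2 (fell by 1.51) and UGT2B11 (adjusted p = 7.27e-13), and Tebuconazole S100P (fell by 1.43), FKBP5 (fell by 1.39) and DIO2 (fell by 1.30). Limma called 0 genes higher in these 6 groups, and 6 lower under BisphenolA (244 at unadjusted p under 0.05), 5 under Prochloraz (192), 5 under Triticonazole, 4 under Linuron (340), 4 under Tebuconazole (93) and 2 under DDE (114). The reduced fit gave higher and lower counts of 37 and 70, 64 and 57, 4 and 43, 34 and 60, 2 and 25, and 0 and 31. Cyclic loess gave upward shares of 10.5% for BisphenolA and 13.3% for Prochloraz.

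Among the steroids and steroid drugs, Mifepristone raised the asparagine synthetase gene ASNS by 1.78 (SE 0.31, adjusted p = 0.000786), the stress transcription factor DDIT3 by 1.71 (SE 0.28) and the glutamine transporter SLC1A5 by 1.23 (SE 0.21), while UGT2B11 fell by 1.23 and DIO2 fell by 1.10. Finasteride, a drug against steroid 5-alpha reductase, raised the cholesterol exporter ABCG1 by 0.89 (SE 0.19, adjusted p = 0.0407), and UGT2B11 (-1.56), DIO2 (-1.41) and S100P (-1.41) fell. Under Dehydroepiandrosterone NDRG1 (-1.90), UGT2B11 (-1.63) and S100P (-1.51) fell, and under Cyproterone acetate UGT2B11 fell by 1.01 (SE 0.13, adjusted p = 2.75e-06). Limma called 7 higher and 2 lower genes under Mifepristone (215 at unadjusted p under 0.05), 1 and 4 under Finasteride (142), 0 and 5 under Dehydroepiandrosterone (153), and 0 and 1 under Cyproterone acetate (120). In the reduced fit the counts were 51 and 51, 13 and 36, 5 and 39, and 12 and 13. Cyclic loess moved the upward share to 16.7% under Cyproterone acetate. Without any 1 of the arrays of Dehydroepiandrosterone the count was 2, without Cyproterone acetate 3 it was 2, and under Finasteride it was 2, 2 and 3 without its arrays 1, 2 and 3.

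Under Progesterone CLDN8, a tight junction gene, fell by 1.25 (SE 0.27, adjusted p = 0.0468), and UGT2B11 fell by 1.06 (SE 0.13). TTC28-AS1 at 0.70, SH2D2A at 0.68 and GPR171 at 0.53 rose, with SDs of 1.05, 1.00 and 0.67 between the 3 arrays. The glucocorticoid Dexamethasone raised the transcription factor gene ATOH8 by 0.97 (SE 0.22, adjusted p = 0.036), the pepsinogen gene PGC by 0.97 (SE 0.14, adjusted p = 1.46e-05) and TERB2 by 0.68 (SE 0.15), with SDs of 0.81 for ATOH8 and 1.07 for TERB2 between the 3 arrays, and no gene list was called under it. Limma called 8 higher and 2 lower genes under Progesterone and 23 and 0 under Dexamethasone, with 618 and 708 at unadjusted p under 0.05, and in the reduced fit 48 and 28, and 161 and 25. Both counts moved with single arrays. Progesterone gave 104, 85 and 1 without its arrays 1, 2 and 3. Dexamethasone gave 192, 6 and 124 without its arrays 1, 2 and 3.

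Apigenin, a plant flavonoid, changed genes beyond those that R1881 raised. The metallothionein genes MT2A and MT1F, whose products bind zinc and copper, rose by 3.54 (SE 0.37, adjusted p = 6.48e-11) and 2.41 (SE 0.24), and ATP5MK, a subunit of mitochondrial ATP synthase, rose by 2.88 (SE 0.26). SGK1 (-3.11, SE 0.43, adjusted p = 5.01e-07), the epithelial transcription factor gene SPDEF (-2.29, SE 0.37) and C1orf116 (-2.25) fell. Of 7 measured genes of the metallothionein list 6 rose, also when adjusted over the list alone (camera, adjusted p = 1.06e-45, and 4.74e-20 with an estimated correlation), among them MT1X at 1.90, MT1G at 1.33 and the zinc exporter SLC30A1 at 1.22, while MT1E at 0.42 did not pass. Limma called 87 genes higher and 175 lower, and 532 and 705 in the reduced fit, which kept 231 of the 262. Without Apigenin 2 and no other array the count was 79.

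Spironolactone, a steroidal diuretic, was called with 1448 genes higher and 1834 lower. MYC (-3.28, SE 0.45, adjusted p = 4.46e-07), FOXA1, a pioneer factor of the androgen receptor (-3.16, SE 0.42), and C19orf48P (-3.14, SE 0.40) fell. AIFM1 at 2.22, ANKRA2 at 1.98 and CSAG1 at 1.91 rose, with SDs of 2.00 and 2.36 between the 3 arrays for AIFM1 and CSAG1 and of 2.13 for FOXA1. Of 16 ribosome biogenesis genes 9 fell, also when adjusted over the list alone, among them NOP16 (fell by 2.22), RRS1 (fell by 2.08) and DKC1 (fell by 1.76), with adjusted p = 5.51e-06, but adjusted p = 0.169 with an estimated correlation. Of 20 mitotic genes 11 fell, or 12 when adjusted over the list alone, among them CDC20 (fell by 1.90), with adjusted p = 5.83e-05, but adjusted p = 0.408 with an estimated correlation. Much of this came with array 2, which stands apart. Without it alone 252 genes were called, and the reduced fit gave 680 higher and 944 lower genes and kept 793 of the 3282. There FOXA1 stood at -1.99, ANKRA2 at 0.97 and CSAG1 at 0.41 (adjusted p = 0.00201), and AIFM1 at 0.36 did not pass (adjusted p = 0.294). The ribosome biogenesis list had a median of -0.44 (adjusted p = 1.54e-06, and 7.27e-06 with an estimated correlation) and the mitotic list of -0.36 (adjusted p = 0.00141, but adjusted p = 0.197 with an estimated correlation). Under cyclic loess 68.2% of the calls were upward, against 44.1%.

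The androgens given with R1881 at 0.5 uM made few changes that did not rest on a single array. Under Testosterone propionate F3, the tissue factor gene, rose by 0.67 (SE 0.15, adjusted p = 0.0259), and by 0.55 in the reduced fit (adjusted p = 0.0202). UBXN7 at 0.70 and MIR335 at 0.65 rose and SOD2 fell by 0.58 in the fit to all arrays, but they stood at 0.11, 0.12 and -0.27 in the reduced fit (adjusted p = 0.893, 0.879 and 0.611). CRYAA at 1.06, GIMAP4 at 0.97 and TBR1 at 0.92 rose under MethylTestosterone, and all of them had adjusted p = 1 in the reduced fit. Under Trenbolone SLC43A1 at 2.16, FOXR1 at 2.16 and SPATA31A1 at 2.07 rose, and EPCAM (-1.79), ETFA (-1.71) and FLRT3 (-1.66) fell, with SDs of 1.60 to 3.69 between its arrays; in the reduced fit FLRT3 had adjusted p = 0.299 and the others adjusted p = 1. Limma called 59 higher and 1 lower genes under Testosterone propionate, 115 and 0 under MethylTestosterone and 1213 and 675 under Trenbolone. The reduced fit called 27 and 0, 0 and 0 (115 of the main calls lost), and 4 and 0, with 4 of 60 and 1 of 1888 calls kept. Without arrays 1, 2 and 3 in turn the counts were 947, 1 and 730 for Testosterone propionate, 707, 0 and 527 for MethylTestosterone and 4488, 1 and 5037 for Trenbolone. Cyclic loess put 98.0% of the Trenbolone calls upward, against 64.2%.

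Androstenedione, Atrazine, Dihydrotestosterone, Iprodione and Norethindrone had 0 genes called by limma, with 68, 71, 148, 90 and 225 genes at unadjusted p under 0.05. The reduced fit gave 8, 1, 5, 0 and 1 genes. Leaving out Dihydrotestosterone 1 or 3 or Norethindrone 1 gave 1 gene. The androgen-induced list was called upward under Dihydrotestosterone (camera, adjusted p = 0.000746, but adjusted p = 0.514 with an estimated correlation).

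The cholesterol synthesis list was called under 12 chemicals of several kinds, 5 of them with an estimated correlation. The 20 measured genes had a median change of 0.75 under Androstenedione (adjusted p = 3.12e-23, and 3.32e-06 with an estimated correlation), with HMGCS1, a synthase of the mevalonate pathway, at 1.15 and INSIG1, a sterol sensor, at 1.45, neither of which passed over all genes. The median was 0.59 under Cyproterone acetate (adjusted p = 2.91e-21, and 7.96e-06 with an estimated correlation) and 0.41 under Mifepristone (adjusted p = 6.68e-09, and 0.00776). The list was also called upward under Progesterone (median 0.42, but adjusted p = 0.0541 with an estimated correlation), BisphenolA (0.38, but adjusted p = 0.0646 likewise) and Dehydroepiandrosterone (0.34, but adjusted p = 0.136 likewise). It was called downward under Flutamide (median -0.61, adjusted p = 1.44e-08, and 0.00963 with an estimated correlation, or -0.43 in the reduced fit, adjusted p = 2.28e-15) and DDE (-0.38, adjusted p = 3.19e-08, and 0.0123). The downward calls under Hydroxyflutamide (-0.28), Atrazine (-0.19), Bicalutamide (-0.16) and Vinclozolin (-0.14) had adjusted p = 0.254, 0.473, 0.3 and 0.427 with an estimated correlation. No member passed over all genes under any chemical named here. When adjusted over the list alone, 1 rose under Androstenedione, Cyproterone acetate and Mifepristone each and 2 under Progesterone, and 2 fell under Flutamide. In the reduced fit 6 members rose under Androstenedione and 6 under Cyproterone acetate.

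Targets of ATF4, the transcription factor of the amino acid response, had a median of 1.00 under Mifepristone (adjusted p = 3.71e-70, and 1.15e-08 with an estimated correlation). Of 23 genes 4 rose, or 13 when adjusted over the list alone, namely ASNS, DDIT3, the glutathione-degrading CHAC1 (1.11, adjusted p = 5.37e-13) and the sestrin gene SESN2 (1.12). The list was called upward under Vinclozolin (0.36, adjusted p = 3.52e-17, and 0.00734 with an estimated correlation), under Prochloraz (0.32, but adjusted p = 0.0667 with an estimated correlation) and under Cyproterone acetate (0.20, but adjusted p = 0.163 likewise), without a member that passed over all genes; adjusted over the list alone, 2, 2 and 1 members rose. The metallothionein list, beyond Apigenin, was called upward under BisphenolA (median 0.49, adjusted p = 1.7e-08, and 3.1e-06 with an estimated correlation), Mifepristone (0.24, adjusted p = 1.5e-05, and 0.000165) and DDE (0.22, adjusted p = 0.000233, and 0.0012), and under Prochloraz (0.10, but adjusted p = 0.0646 likewise). The unfolded protein response list had a median of 0.28 under BisphenolA with all 15 genes positive (adjusted p = 3.19e-08, and 0.034 with an estimated correlation).

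**Figure D4:**
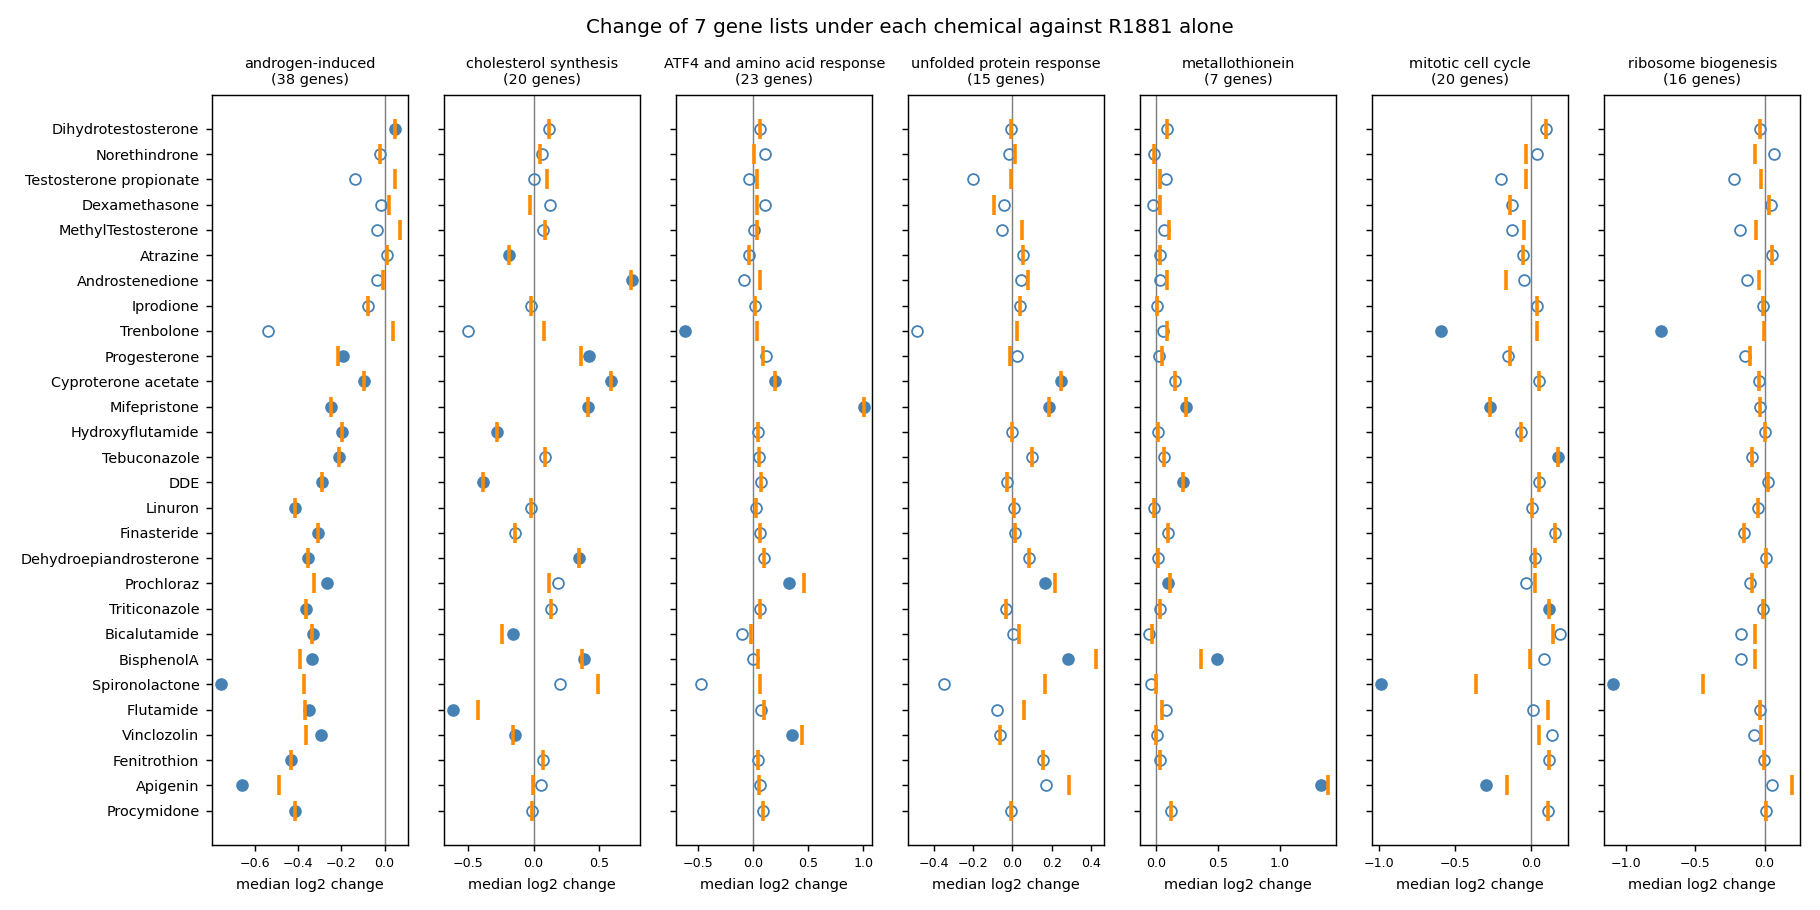
Median log2 change of 7 gene lists (horizontal axes) under each chemical against R1881 alone, with filled circles where camera at the preset correlation called the list, open circles where it did not, and bars for the reduced fit. Cholesterol synthesis runs from -0.61 under Flutamide to 0.75 under Androstenedione, and ATF4 targets reach 1.00 under Mifepristone.

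In all, camera called 119 of 783 combinations of list and comparison, of which 45 were called with an estimated correlation, and fry called 34. Of the 74 calls lost with an estimated correlation, 39 were called with it in the reduced fit. The glucocorticoid response list was called downward under 16 chemicals and upward under Dihydrotestosterone (adjusted p = 0.0169, but adjusted p = 0.642 with an estimated correlation), and the hypoxia and glycolysis list downward under 15. With an estimated correlation the glucocorticoid list was called downward under 12, but not under Apigenin (adjusted p = 0.557), DDE (adjusted p = 0.0541), Hydroxyflutamide (adjusted p = 0.0607) and Spironolactone (adjusted p = 0.211), all of them among these 39, and the hypoxia list was called under 2, Bicalutamide (adjusted p = 0.0152) and Finasteride (adjusted p = 0.0407). NDRG1 fell by 2.45 under Bicalutamide, and under Finasteride 0 members passed over all genes by limma and 1 fell when adjusted over the list alone.

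Related chemicals were compared directly at equal dose, 3 arrays against 3, where the exact test cannot go below 0.1. Hydroxyflutamide carries a hydroxyl group that Flutamide lacks. At 20 uM the index under Flutamide minus that under Hydroxyflutamide was -0.25 (95% interval -0.60 to 0.11), limma called 0 genes (696 at unadjusted p under 0.05), and in the reduced fit the difference was -0.31 (-0.45 to -0.18) with 3 genes. Flutamide minus Bicalutamide was 0.0048 (-0.35 to 0.36) with 0 genes (643 unadjusted), and Hydroxyflutamide minus Bicalutamide was 0.25 (-0.11 to 0.61) with 0 genes (217), or 0.27 (0.15 to 0.39) with 2 genes in the reduced fit. Without Flutamide 1 or 2 the Flutamide pairs gave 13 and 14 genes against Hydroxyflutamide and 13 and 18 against Bicalutamide. The imidazole Prochloraz and the triazole Tebuconazole gave 0 genes (47), with an interval for Tebuconazole minus Prochloraz of -0.25 to 0.46.

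The dichlorophenyl dicarboximides differed among themselves at 20 uM. SGK1 was lower under Vinclozolin than under Iprodione (-2.53 on the log2 scale, SE 0.49, adjusted p = 0.012) and lower under Procymidone than under Iprodione (-2.93, SE 0.49, adjusted p = 0.000675). FKBP5 differed by -1.73 between Vinclozolin and Iprodione, and C1orf116 by -2.26 between Procymidone and Iprodione. The index differed by -0.53 (-0.89 to -0.17) and by -0.63 (-0.99 to -0.28), with 4 and 6 genes called and 42 and 58 in the reduced fit. Without Iprodione 2 the counts were 1 and 3, and without Vinclozolin 1 or 3 or Iprodione 1 the first was 2. Vinclozolin and Procymidone gave 0 genes (102) and a difference of 0.10 (-0.25 to 0.46).

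Among the steroids at 10 uM, S100P was higher under Dexamethasone than under Mifepristone, which has a dimethylaminophenyl group, by 1.98 (SE 0.32, adjusted p = 0.000162) and higher than under Progesterone by 1.71 (SE 0.32, adjusted p = 0.00462). UGT2B11 was higher by 1.32 under Dexamethasone than under Mifepristone, and DDIT3 (-1.74) and SLC1A5 (-1.45) were lower. DDIT3 (-1.62) and CHAC1 (-0.99) were lower and ABCG1 (1.16) and PCDHGB4 (0.51) higher under Progesterone than under Mifepristone. PGC was higher (1.24) and PCDHGB4 (-0.55) and SAG (-0.47) lower under Dexamethasone than under Progesterone. ABCG1 (1.16) was also higher and UGT2B11 (-0.87) lower under Progesterone than under Androstenedione, which has a 17-ketone in place of the acetyl group. The counts were 17, 12, 8 and 2 for Dexamethasone against Mifepristone and Progesterone, and Progesterone against Mifepristone and Androstenedione, and 147, 127, 40 and 11 in the reduced fit. Dexamethasone against Mifepristone gave 124 and 11 without Dexamethasone 1 and 2 and 74 without Dexamethasone 3, and 7 and 10 without Mifepristone 1 and 2. Dexamethasone against Progesterone gave 113, 6 and 59 without Dexamethasone 1, 2 and 3, and 72, 53 and 3 without Progesterone 1, 2 and 3. Progesterone against Mifepristone gave 74, 52 and 3 without Progesterone 1, 2 and 3, and 2, 3 and 4 without Mifepristone 1, 2 and 3. Progesterone against Androstenedione gave 51, 39 and 0 without Progesterone 1, 2 and 3, and 0, 0 and 1 without Androstenedione 1, 2 and 3. Dehydroepiandrosterone and Finasteride, a 4-azasteroid, differed in ABCG1 (-1.17, SE 0.22, adjusted p = 0.02) as the 1 gene called, with 4 in the reduced fit. Without Finasteride 3 there were 2, and without any other single array of either there were 0. Their index difference was -0.062 (-0.42 to 0.29).

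Cyproterone acetate and Spironolactone differed in the most genes of the 19 pairs in the fit to all arrays, with MYC higher by 3.23 (SE 0.53, adjusted p = 3.27e-05) and FOXA1 by 3.18 (SE 0.49) under Cyproterone acetate, and 2168 genes called. There were 982 in the reduced fit and 93 without Spironolactone 2. The index difference was 0.62 (0.27 to 0.98), or 0.33 (0.19 to 0.47) in the reduced fit. AIFM1 (-2.17) and MIR526A2 (-2.06) were lower under Cyproterone acetate in the fit to all arrays, but AIFM1 stood at -0.31 (adjusted p = 0.58) and FOXA1 at 2.01 in the reduced fit, and without the 6 arrays MIR526A2 stood at 0.027 (adjusted p = 0.992). Without Spironolactone 1 or 3 the counts were 3695 and 3779, and without Cyproterone acetate 1 or 2 they were 1060 and 862.

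Among the androgens at 0.5 uM the counts depended on single arrays. Dihydrotestosterone against MethylTestosterone, which has a 17-alpha methyl group, gave 1 gene (MIR96, -0.60) and an index difference of 0.20 (-0.16 to 0.55), or 0 genes and 0.053 (-0.085 to 0.19) in the reduced fit. Dihydrotestosterone against the ester Testosterone propionate gave 8 genes, among them ZNF843 (-0.58) and IL20RB (-0.55), and 7 in the reduced fit, where these 2 had adjusted p = 0.8 and 0.398, with 0.055 (-0.083 to 0.19). MethylTestosterone against Testosterone propionate gave 21 genes, with KDM1B (0.99), ZNF625 (0.90), LOC105369266 (-0.86) and KCNN1 (-0.71) among the largest, but 1 in the reduced fit, where these 4 had adjusted p = 1. Trenbolone against Norethindrone, both 19-nor steroids, gave 215, with E2F1 (1.43), FAAHP1 (1.39), FLRT3 (-1.74) and MAGED1 (-1.52) among the largest, but 1 in the reduced fit, where these 4 had adjusted p = 1. The index difference was -0.37 (-0.72 to -0.0089), or 0.099 (-0.040 to 0.24) in the reduced fit. Trenbolone against Dihydrotestosterone gave 0 genes (3436 unadjusted) and -0.50 (-0.86 to -0.14), or 0 and -0.017 (-0.15 to 0.12) in the reduced fit, and Norethindrone against MethylTestosterone gave 1 (MIR96, -0.63) and 0. For Dihydrotestosterone against MethylTestosterone the counts were 0 without any 1 array of Dihydrotestosterone and 372, 0 and 331 without MethylTestosterone 1, 2 and 3. For Dihydrotestosterone against Testosterone propionate they were 1, 0 and 0 without Dihydrotestosterone 1, 2 and 3, and 408, 2 and 338 without Testosterone propionate 1, 2 and 3. MethylTestosterone against Testosterone propionate gave 398, 4 and 373 without the arrays of MethylTestosterone, and 416, 0 and 349 without those of Testosterone propionate. Trenbolone against Norethindrone gave 3483, 1 and 4883 without the arrays of Trenbolone, and 1, 2 and 1 without those of Norethindrone.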

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

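The test of Flutamide 3, that of slopes between arrays of a chemical and both tests of the clusters given here were chosen only after the results were seen. Among 117 values checked for a single array far from the other 5 of its group, 5 had such an array, and chance alone, at about 1 in 20, would give 5.85.

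SLC43A1, an amino acid transporter gene, stood at 7.54 in R1881 2b against 6.65 to 6.88 in the other R1881 arrays, and this gap made up 0.741 of the range of the group. SPATA31A1 stood at 7.03 in the same array against 6.58 to 6.69 (0.763 of the range). The genes of cholesterol synthesis had a mean of 9.21 in R1881 2b against 9.29 to 9.34 (0.626). In R1881 1b, UBXN7 stood at 7.15 against 6.75 to 6.86 (0.709) and TBR1, a brain transcription factor gene, at 6.85 against 6.56 to 6.67 (0.642). No explanation was tested for these 5 values.

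Luminal epithelium markers in the 6 arrays that stand apart from their cluster lay at -2.82 to -0.65 (-1.18 in Flutamide 3), but at -0.0067 in MethylTestosterone 2. Basal, stromal, leukocyte or neuroendocrine markers were above the 95th percentile of random lists in 0 of the 6 arrays, which argues against RNA of these other cell types. A chemical effect alike in 3 arrays is not the whole cause. The other 12 arrays deviated with slopes of at most 0.215 on these 6 across genes, where 1 would be alike. An effect in 1 culture alone stays open: the median correlation of the 6 arrays with the other arrays of their chemical was -0.0218, between the median (-0.0818) and the highest (0.524) of those with other chemicals. A fault common to these arrays may account for 5 of them, as the deviations correlated across genes with a median of 0.392 over the 15 pairs. Flutamide 3 correlated at most 0.0559 with the other 5, so a shared fault is excluded for it, and its cause was not found.

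Ribosome biogenesis, cholesterol synthesis and ATF4 target genes had median differences of 0.28, 0.195 and 0.225 between cluster B and cluster A (B minus A), while p53 targets stood at -0.165. The first principal component held 37.7% of the variance over all arrays and 59.2% without the 6 arrays. The number in the labels is excluded as the whole cause, because 20 arrays lay outside the main cluster of their number. A swap of numbers 1 and 3 in some groups is excluded as the whole cause too, since 10 chemicals had both arrays in the same cluster, 6 in A and 4 in B. The labels do not say which array belongs to which day, so a day effect could not be tested, and no biological explanation was tested.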

How the results depend on the processing

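The settings without 2, 6 or 7 arrays, those with the cluster as a block and that with same-numbered controls averaged were chosen after seeing the data; the others were planned. In what follows each value under a setting stands against that from all 96 arrays, which is not given again for a count of genes once it has been, and the cause of a difference was not tested unless one is named. Signal over background limits the dim genes: the background of the deposited values is not known, and under a stricter filter 11 named gene calls ended while 79 held. Without a filter all 29 gene counts stayed within 1.5-fold and 1 named call ended, that of STEAP1 under R1881 (adjusted p = 0.0515). Swapping the controls used to select and to measure left all 28 shares within 1 SD.

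Cyclic loess with median centring gave 56 genes for R1881 against DMSO in place of 23. Apigenin gave 623 against 262, Atrazine 1 against 0, Bicalutamide 19 against 8, BisphenolA 19 against 6, Cyproterone acetate 6 against 1, DDE 6 against 2, Dehydroepiandrosterone 14 against 5, Fenitrothion 31 against 9 and Finasteride 10 against 5. Flutamide gave 47 against 10, Hydroxyflutamide 6 against 2, Linuron 16 against 4, Mifepristone 26 against 9, Prochloraz 15 against 5, Procymidone 25 against 9, Testosterone propionate 27 against 60, Trenbolone 894 against 1888 and Triticonazole 11 against 5. Vinclozolin gave 27 against 8. Another 9 gene counts and 10 pair counts stayed within 1.5-fold. Flutamide and Hydroxyflutamide gave 1 against 0, Procymidone and Iprodione 12 against 6, Dihydrotestosterone and MethylTestosterone 0 against 1, Dihydrotestosterone and Testosterone propionate 3 against 8 and MethylTestosterone and Testosterone propionate 61 against 21. Trenbolone and Norethindrone gave 5 against 215, Norethindrone and MethylTestosterone 0 against 1, Progesterone and Mifepristone 14 against 8 and Cyproterone acetate and Spironolactone 1412 against 2168. The index difference was 0.019 against -0.010 for Dexamethasone, -0.091 against -0.066 for Iprodione, 0.059 against -0.082 for MethylTestosterone and 0.043 against -0.39 for Trenbolone. The share of the response left was 9.3% against -1.9% for Apigenin, 20.9% against 25.9% for Dehydroepiandrosterone, 13.3% against 7.2% for Flutamide, 86% against 95.1% for Iprodione and 20.2% against 23.5% for Triticonazole. Of the named genes 112 held their call and 14 lost it.

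Leaving out the 6 arrays gave 82 genes for R1881 against DMSO. Apigenin gave 467, Atrazine 1, Bicalutamide 41, BisphenolA 42, Cyproterone acetate 9, DDE 12, Dehydroepiandrosterone 22, Dexamethasone 184 against 23 and Dihydrotestosterone 3 against 0. Fenitrothion gave 47, Finasteride 21, Flutamide 29, Hydroxyflutamide 17, Linuron 37, MethylTestosterone 0 against 115, Mifepristone 42, Norethindrone 1 against 0 and Prochloraz 25. Procymidone gave 50, Progesterone 43 against 10, Spironolactone 871 against 3282, Tebuconazole 10 against 4, Testosterone propionate 24, Trenbolone 5, Triticonazole 17 and Vinclozolin 47. Of the named genes 101 held and 26 lost their call. MIR526A2, called at -2.06 between Cyproterone acetate and Spironolactone, stood at 0.027, which follows from the loss of Spironolactone 2.

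With the cluster as a block as well, R1881 against DMSO gave 183 genes. Androstenedione gave 8 against 0, Apigenin 1237, Atrazine 1, Bicalutamide 79, BisphenolA 107, Cyproterone acetate 25, DDE 31, Dehydroepiandrosterone 44 and Dexamethasone 186. Dihydrotestosterone gave 5, Fenitrothion 102, Finasteride 49, Flutamide 62, Hydroxyflutamide 37, Linuron 94, MethylTestosterone 0, Mifepristone 102 and Norethindrone 1. Prochloraz gave 121, Procymidone 132, Progesterone 76, Spironolactone 1624, Tebuconazole 27, Testosterone propionate 27, Trenbolone 4, Triticonazole 47 and Vinclozolin 99. Flutamide and Hydroxyflutamide gave 3, Hydroxyflutamide and Bicalutamide 2 against 0, Vinclozolin and Procymidone 4 against 0, Vinclozolin and Iprodione 42 against 4 and Procymidone and Iprodione 58. Tebuconazole and Prochloraz gave 2 against 0, Dihydrotestosterone and MethylTestosterone 0, MethylTestosterone and Testosterone propionate 1, Trenbolone and Norethindrone 1 and Norethindrone and MethylTestosterone 0. Progesterone and Androstenedione gave 11 against 2, Progesterone and Mifepristone 40, Dexamethasone and Mifepristone 147 against 17, Dexamethasone and Progesterone 127 against 12 and Cyproterone acetate and Spironolactone 982. Dehydroepiandrosterone and Finasteride gave 4 against 1. The index difference was -0.014 against 0.0047 for Androstenedione, 0.0084 against -0.010 for Dexamethasone, -0.066 against -0.066 for Iprodione, 0.061 against -0.082 for MethylTestosterone, 0.059 against -0.21 for Testosterone propionate and 0.096 against -0.39 for Trenbolone. Shares of the response left were 10.5% against -1.9% for Apigenin, 97.4% against 109% for Dexamethasone, 105.2% against 111.1% for Norethindrone and 25% against 23.5% for Triticonazole. Camera turned its direction for 6 lists that it had called with all arrays. The luminal epithelium markers under Flutamide had a median of 0.0991 against -0.41. Under Trenbolone the ATF4 list had 0.034 against -0.62, fatty acid synthesis 0.0051 against -0.79, and the mitotic list 0.039 against -0.59. Ribosome biogenesis under Trenbolone at -0.0078 against -0.75 and DNA replication under Spironolactone at -0.058 against -0.76 turned in camera's comparison with other genes, but not in the sign of the median. A further 9 list calls were lost and 104 held, and 27 named genes lost their call while 101 held it.

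Control arrays 1 to 3 alone, a setting with fewer controls, gave 5 genes for R1881 against DMSO. Apigenin gave 90, DDE 1, Dehydroepiandrosterone 2, Dexamethasone 3, Finasteride 2, Flutamide 4, Hydroxyflutamide 1, MethylTestosterone 0 and Prochloraz 2. Progesterone gave 1, Spironolactone 1943, Tebuconazole 1, Testosterone propionate 3, Trenbolone 2, Triticonazole 2 and Vinclozolin 4. The index difference was -0.027 against 0.0047 for Androstenedione, -0.098 against -0.066 for Iprodione and -0.42 against -0.39 for Trenbolone. Control arrays 1b to 3b alone gave 6 genes for R1881 against DMSO. Apigenin gave 87, Bicalutamide 4, DDE 1, Dehydroepiandrosterone 2, Dexamethasone 1, Fenitrothion 5, Finasteride 2, Flutamide 5 and Hydroxyflutamide 1. Linuron gave 2, MethylTestosterone 0, Prochloraz 2, Progesterone 1, Spironolactone 1793, Tebuconazole 1, Testosterone propionate 2, Trenbolone 2 and Triticonazole 2. Vinclozolin gave 4. Here the index difference was 0.027 against -0.0049 for Atrazine, 0.022 against -0.010 for Dexamethasone and 0.011 against -0.021 for Norethindrone. Named genes lost 46 and 47 calls in these fits and kept 47 and 46.

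Control arrays of the same number were averaged as 1 sample each, since 1b to 3b may repeat 1 to 3. R1881 against DMSO then gave 5 genes. Apigenin gave 76, Bicalutamide 4, DDE 1, Dehydroepiandrosterone 2, Dexamethasone 1, Fenitrothion 5, Finasteride 2, Flutamide 5, Hydroxyflutamide 1 and MethylTestosterone 0. Prochloraz gave 2, Procymidone 5, Progesterone 1, Spironolactone 1800, Tebuconazole 1, Testosterone propionate 3, Trenbolone 2, Triticonazole 2 and Vinclozolin 4. Another 9 counts stayed within 1.5-fold, 46 calls of named genes held and 47 were lost. All 28 camera tests of the androgen-induced list, adjusted over the 28 chemicals, were the same. The exact test of the index cannot go below 0.1 with 3 controls.

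Fitting only the groups compared gave 62 genes for R1881 against DMSO. Bicalutamide gave 19, BisphenolA 17, Cyproterone acetate 4, Dexamethasone 0, Finasteride 8, Flutamide 6, MethylTestosterone 0, Prochloraz 11 and Procymidone 19. Progesterone gave 0, Spironolactone 161, Testosterone propionate 0, Trenbolone 0 and Triticonazole 12. Of the named genes 37 lost their call and 56 held. With the stricter filter Dehydroepiandrosterone gave 8, Dexamethasone 2, Hydroxyflutamide 1, MethylTestosterone 0, Progesterone 1 and Testosterone propionate 2. When every probe was tested Dexamethasone gave 43, Hydroxyflutamide 4, MethylTestosterone 200 and Testosterone propionate 107. Camera with an estimated correlation called 45 combinations of list and comparison, and fry 34, against 119.

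The number as a replicate block moved 8 gene counts by over 1.5-fold and 21 by less. BisphenolA gave 11, Cyproterone acetate 2, Dehydroepiandrosterone 9, Fenitrothion 15, Flutamide 22, Procymidone 14, Testosterone propionate 113 and Vinclozolin 14. Of these, BisphenolA, Flutamide, Testosterone propionate and Vinclozolin are not among the 12 chemicals whose numbers were taken to pair the arrays. In 8 chemicals every array was closest to its own number. MethylTestosterone and Testosterone propionate gave 39, Trenbolone and Dihydrotestosterone 507 against 0 and Trenbolone and Norethindrone 719. The share left was 5.7% against -1.9% for Apigenin, 4.8% against 12.5% for Bicalutamide, 17.9% against 25.9% for Dehydroepiandrosterone, 21.6% against 31.1% for Linuron and 18.1% against 23.5% for Triticonazole. SAG lost its call between Dexamethasone and Progesterone (-0.47, adjusted p = 0.0519), and the block changed no other call, neither of the 127 other named genes nor of the androgen-induced list.

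Before the limit of 0.9 was settled, R1881 against DMSO was also fitted without 2 arrays (43 genes), without 2 arrays and with the replicate block (56), and without 7 arrays (90), with the cluster (217) or the cluster and number (240) as blocks. With adjustment over the 28 chemicals alone, the androgen-induced list under Iprodione was called by camera under loess (adjusted p = 0.00288), with controls 1 to 3 (0.00528) and in the reduced fit (0.0316), but not with all arrays (0.073), controls 1b to 3b (0.671) or the replicate block (0.0954). Over the same settings the adjusted p under Trenbolone ranged from 2.05e-05, upward in the reduced fit, over 0.0276, downward with controls 1 to 3, to 0.696 under loess. Over all 783 combinations Iprodione was not called with all arrays (adjusted p = 0.206) or in the reduced fit (adjusted p = 0.111, and 0.59 with an estimated correlation), and Trenbolone, at 0.17 with all arrays, was called upward in the reduced fit (adjusted p = 0.000167), but not with an estimated correlation (0.135).

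Leaving out 1 array at a time, as the lowest and the highest value, moved these counts of changed genes. Apigenin gave 79 to 338, Bicalutamide 4 to 9, Cyproterone acetate 1 to 2, DDE 1 to 3, Dehydroepiandrosterone 2 to 6 and Dexamethasone 6 to 192. Dihydrotestosterone gave 0 to 1, Fenitrothion 5 to 11, Finasteride 2 to 5, Flutamide 6 to 226, Hydroxyflutamide 1 to 24 and Linuron 2 to 41. MethylTestosterone gave 0 to 707, Norethindrone 0 to 1, Prochloraz 2 to 5, Procymidone 5 to 10, Progesterone 1 to 104 and Spironolactone 252 to 4595. Tebuconazole gave 1 to 4, Testosterone propionate 1 to 947, Trenbolone 1 to 5037, Triticonazole 2 to 6 and Vinclozolin 4 to 8. The counts between chemicals ranged likewise. Flutamide and Hydroxyflutamide gave 0 to 14, Flutamide and Bicalutamide 0 to 18, Hydroxyflutamide and Bicalutamide 0 to 5 and Vinclozolin and Iprodione 1 to 3. Procymidone and Iprodione gave 3 to 5, Dihydrotestosterone and MethylTestosterone 0 to 372, Dihydrotestosterone and Testosterone propionate 0 to 408 and MethylTestosterone and Testosterone propionate 0 to 416. Trenbolone and Dihydrotestosterone gave 0 to 3833, Trenbolone and Norethindrone 1 to 4883, Norethindrone and MethylTestosterone 0 to 357 and Progesterone and Androstenedione 0 to 51. Progesterone and Mifepristone gave 2 to 74, Dexamethasone and Mifepristone 7 to 124, Dexamethasone and Progesterone 3 to 113 and Cyproterone acetate and Spironolactone 93 to 3779. Dehydroepiandrosterone and Finasteride gave 0 to 2. MIR526A2 ranged from -3.14 to 0.027.

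The index difference ranged as follows when 1 array was left out, with array 2 behind the highest value of the last 3. Androstenedione gave -0.024 to 0.032, Atrazine -0.036 to 0.033, Dexamethasone -0.040 to 0.023 and Iprodione -0.088 to -0.045. MethylTestosterone gave -0.17 to 0.070, Testosterone propionate -0.35 to 0.040 and Trenbolone -0.64 to 0.11. Shares of the response left had these ranges. Dehydroepiandrosterone gave 19.2% to 27.4%, Finasteride 24.3% to 33.7%, Flutamide 3.1% to 14.6% and MethylTestosterone 104% to 119.5%. Norethindrone gave 108.1% to 114.5%, Tebuconazole 35.9% to 45.7%, Testosterone propionate 105.1% to 129.9% and Triticonazole 17.7% to 25%. In these fits 252 calls of a named gene in a comparison were lost, 833 held and 1 turned. Of camera's tests of the androgen-induced list, the 1 list run, 229 held, 15 turned in sign and 8 became calls with adjustment over the 28 chemicals.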

Other observations

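The tests of Apigenin and Spironolactone with the number as a further block and with the R1881 arrays split by number were added after other values of that pattern were seen, and the reduced fit, without the 6 arrays and with the cluster as a block, was itself chosen after seeing the data.

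Genes of the unfolded protein response, which act in protein folding in the endoplasmic reticulum, had a positive change in all 15 members under Cyproterone acetate (median 0.25, camera, adjusted p = 9.99e-07, but adjusted p = 0.0667 with an estimated correlation). They were also called upward under Prochloraz (0.17, but adjusted p = 0.351 with an estimated correlation) and Mifepristone (0.19, but adjusted p = 0.487 likewise), with 0 members past limma's threshold, also when adjusted over the list alone. Liver X receptor targets, which handle sterols, had a median of 0.24 under Finasteride (adjusted p = 0.000101, but adjusted p = 0.117 with an estimated correlation), where ABCG1 rose by 0.89. Under Progesterone their median was 0.25 (adjusted p = 0.00468, but adjusted p = 0.307 with an estimated correlation), with ABCG1 at 0.80 (adjusted p = 0.0888) and SREBF1 at 0.99 (adjusted p = 0.991). Fatty acid synthesis genes were called upward under Androstenedione (0.21), Cyproterone acetate (0.18) and Mifepristone (0.23), and downward under DDE (-0.15), with adjusted p = 0.244, 0.281, 0.487 and 0.539 with an estimated correlation.

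Mitotic genes had a median of -0.27 under Mifepristone (adjusted p = 3.65e-05, but adjusted p = 0.38 with an estimated correlation), among them KIF20A at -0.64 and AURKA at -0.43, and 0 of 20 passed by limma over all genes or adjusted over the list alone. Under Apigenin the median was -0.29 (adjusted p = 0.677 with an estimated correlation), with 1 gene that fell and 2 adjusted over the list alone. Under Tebuconazole (0.17) and Triticonazole (0.12) the list was called upward, with 18 of 20 changes positive under each (adjusted p = 0.58 and 0.788 with an estimated correlation). Targets of the aryl hydrocarbon receptor, which induces enzymes of xenobiotic metabolism, were called downward under Progesterone (-0.19), Dehydroepiandrosterone (-0.14), Cyproterone acetate (-0.064) and Finasteride (-0.044), with adjusted p = 0.107, 0.166, 0.143 and 0.0796 with an estimated correlation. Estrogen response genes had a median of 0.11 under Fenitrothion (adjusted p = 0.0189, and adjusted p = 0.0435 with an estimated correlation) and of 0.061 under BisphenolA (adjusted p = 0.0488, but adjusted p = 0.0908 with an estimated correlation), and neither was called in the reduced fit (adjusted p = 0.0518 and 0.0835) or by fry.

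Apigenin and Spironolactone changed many genes alike in the reduced fit, where 209 genes were higher under both and 341 lower. With the R1881 arrays split, their correlation across genes (0.474, the mean of both ways to assign the 2 parts) was the highest of 378 pairs of chemicals (median 0.0969; BisphenolA and Fenitrothion 0.469). With all R1881 arrays r was 0.570 against 0.252 in simulated unchanged groups. With them split the covariance was 0.0395, above the simulated highest of 0.00126. If arrays 1b to 3b repeat 1 to 3 that split is not independent. Split by number, the lowest covariance of 6 ways was 0.0175, above the simulated highest in each. The covariance was 0.0360 without R1881-responsive genes (simulated highest 0.00102) and 0.0375 with the number as a further block (0.00116). In the first split simulated r was at most 0.0347, under the pairs' median. Shared R1881 arrays, a common loss of androgen response and the remaining arrays 1 and 3 thus stay open. Immediate early genes lay at percentile 83.7 of random lists under Spironolactone (but MYC fell) and 54.7 under Apigenin. A loss of short-lived RNA stays open. A response common to both chemicals beyond the androgen receptor may remain as a hypothesis, found and tested on the same data and resting on 2 arrays of each chemical.

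Other splits of the same arrays were compared with the real groups, with all 6 arrays of a control as separate samples; if 1b to 3b repeat 1 to 3, 10 splits remain, too few to exclude chance. For R1881 against DMSO chance can be excluded, with 23 genes against 1 in the highest of 100 splits drawn from 462, and 1 of the 28 splits that part as many pairs reached 23, the real one. Unadjusted, under 5% of splits were as large for 18 of 28 chemicals. The real count and the highest other were 262 and 22 for Apigenin, 8 and 0 for Bicalutamide, 6 and 1 for BisphenolA, 2 and 0 for DDE, 5 and 1 for Dehydroepiandrosterone, and 9 and 0 for Fenitrothion. They were 5 and 1 for Finasteride, 4 and 1 for Linuron, 9 and 2 for Mifepristone, 5 and 0 for Prochloraz, 9 and 1 for Procymidone, 4 and 1 for Tebuconazole, 5 and 0 for Triticonazole and 8 and 0 for Vinclozolin. In these 14 only 1 of 84 was as large, the real one. It was 2 of 84 for Cyproterone acetate (1, 101) and Spironolactone (3282, 3672). It was 3 of 84 for Flutamide (10, 162) and Hydroxyflutamide (2, 3). Chance cannot be excluded for Dexamethasone (5 of 84; 23, 56), Progesterone (7 of 84; 10, 31), Testosterone propionate (11 of 84; 60, 284), Trenbolone (19 of 84; 1888, 4212) and MethylTestosterone (28 of 84; 115, 642). Androstenedione, Atrazine, Dihydrotestosterone, Iprodione and Norethindrone had 0 genes by limma and 84 of 84 splits as large, with a highest other of 0, 0, 1, 1 and 1.

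Splits that called several times the real count, as under Cyproterone acetate, Flutamide, MethylTestosterone, Progesterone and Testosterone propionate, point to a structure of the samples, and so do those of most androgen pairs and of Dexamethasone against Mifepristone and Progesterone. For the chemicals whose numbers were taken to pair the arrays, 1 of the 27 splits that part as many pairs was as large. Atrazine and Iprodione were the exception (27 of 27). The highest other was 6 under Apigenin and 0 otherwise. Other splits group arrays of the same number, and with the replicate block Cyproterone acetate gave 2 genes. Camera on the genes' statistics, adjusted over the 28 chemicals alone, called 113 gene lists (114 of 756 in the main test). The highest other of 100 splits gave 52, but all 28 share the R1881 arrays, so this does not exclude chance. Nor does the number of lists called in R1881 against DMSO, 5 (6 of 100, highest other 7). That count does not test the androgen-induced list itself (exact permutation test of the index, p = 0.002165).

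For the pairs of chemicals the 10 splits are too few for a share under 0.05. The real count and the highest other were 0 and 7 for Flutamide and Hydroxyflutamide, 0 and 0 for Flutamide and Bicalutamide, 0 and 1 for Hydroxyflutamide and Bicalutamide, and 0 and 1 for Vinclozolin and Procymidone. Vinclozolin and Iprodione gave 4 and 0 (1 split as large), Procymidone and Iprodione 6 and 0, and Tebuconazole and Prochloraz 0 and 0 (10 splits). Dihydrotestosterone and MethylTestosterone gave 1 and 130 (7 splits), Dihydrotestosterone and Testosterone propionate 8 and 17 (5), MethylTestosterone and Testosterone propionate 21 and 2604 (9), Trenbolone and Dihydrotestosterone 0 and 1549, Trenbolone and Norethindrone 215 and 1172, and Norethindrone and MethylTestosterone 1 and 71 (8). Progesterone and Androstenedione gave 2 and 0, Progesterone and Mifepristone 8 and 0, Dexamethasone and Mifepristone 17 and 140 (2), Dexamethasone and Progesterone 12 and 218 (6), Cyproterone acetate and Spironolactone 2168 and 2430, and Dehydroepiandrosterone and Finasteride 1 and 0.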
